A study of Drosophila melanogaster with 6 samples.

How the data were processed

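The series profiled poly(A) RNA of male *Drosophila melanogaster* carrying an inducible RNA interference construct against Ugt35b under Repo-GeneSwitch, a pan-glial driver that is active only when the drug RU486 is fed. Flies given RU486 were compared at day 10 with flies of the same genotype given the solvent ethanol (EtOH), with 3 libraries per group. Per the labels' protocols, each library came from 10 flies and 500 ng of total RNA, and was made with a stranded mRNA kit. The sample labels name the tissue as head, whereas the extraction protocol names brains. The labels do not say that the 3 libraries of a group came from separate vials or matings, so p-values measure the spread between these libraries, which may be partly technical.

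The deposited table held raw read counts per gene for 17753 FlyBase gene identifiers, one column per library, and the authors had applied no normalisation to it, per the file headers. The submitters' processing notes name the genome build BDGP6. The aligner, the counting program, its strand setting and the annotation release are not given in the sources used here. The values themselves hold a trace of the counting. Of the 1001 protein-coding genes whose whole span lies inside another protein-coding gene on the other strand, 1001 had no count in any library, and of 845 inside one on the same strand, 839 had none. Among 11903 protein-coding genes outside other genes, 969 had none. A count of 0 for a gene inside another gene therefore says nothing about its expression, and these genes were treated as not measured. They include the glial genes moody, alrm and Tret1-1, the photoreceptor gene Arr2, and Def, Mtk, Ilp2, Ilp3, Ilp5 and fabp. Genes inside others on the opposite strand had no counts either, so strand appears not to have been used, and the level of a gene that partly overlaps another may rest on its unshared part alone.

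Total counts were 12455812, 11689966 and 12636787 in EtOH replicates 1 to 3 and 10389133, 10633167 and 10156909 in RU486 replicates 1 to 3. The deposited name column was empty for 15438 rows. Symbols were therefore looked up by identifier in a FlyBase symbol table, which matched 17626 identifiers. Ugt35b is listed there under the symbol Ugt35B1. Coordinates came from the Ensembl release 115 annotation of build BDGP6.54 and are 1-based, and exonic lengths were the union of annotated exons. Lengths were known for 8877 of the 8945 genes tested.

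Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default minimum count of 10, which left 8945 genes, and libraries were scaled by TMM factors. The test was edgeR's two-sided quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are RU486 minus EtOH, and their standard error (SE) was taken as the size of the log2 fold change divided by the square root of the F statistic. Levels are counts per 1000000 (CPM) computed from the deposited counts with the TMM factors, as mean ± SD of 3 libraries. Sums over the gut and male reproductive tract lists took all genes of the list in the table, tested or not, per 1000000 total counts of a library without TMM factors. No 2 libraries agreed within sampling noise, so none was counted as a repeat of another.

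For genes grouped by function or cell type, 30 lists were fixed before the data were examined, together with the test, the alternatives and the rule for named genes. The rule took Ugt35b, the 10 called genes with the largest rise and the 10 with the largest fall among those with a mean log2 CPM of at least 1 and no overlap between groups, up to 4 members with the smallest p of each list described, and any gene above 2% of a library. Genes named outside the rule were chosen after their values were seen: bdl, repo, Eaat1, Gs2 and nrv2 among glial markers, Ugt35E2, AstC, Drs and Dgat2, the genes of the 6 pathway lists given under other observations, and those named here as not measured. Lists with at least 5 measured members were tested with camera from limma 3.58.1 at its preset correlation of 0.01, adjusted over 28 lists. The lists for Turandot stress genes, with 3 measured members, and for the male reproductive tract, with 0 measured of 20, were too small. Camera was repeated with a correlation estimated per list, and fry was run beside it. Camera compares a list with the other genes, whereas fry asks whether a list's genes move on balance one way and compares them with no other genes, so the 2 p-values answer different questions.

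Alternatives were DESeq2 1.42.0 size factors, library size alone, upper-quartile factors, no filter or a stricter filter of at least 1 CPM in 3 libraries, a robust prior, a replicate block, the DESeq2 Wald test, limma-voom, thresholds of 0.01 and 0.1, removal of the 10 most abundant genes, and each library left out in turn. The procedure was tested on counts simulated for this comparison with 200 changed genes. Over the 8877 simulated genes that passed the filter, it recovered 43.9% of genes changed 1.5-fold, 83.1% of those changed 2-fold and 98.4% of those changed 4-fold. It made 159 calls there, of which 15 were false.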

Results

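The data were 6 RNA-seq libraries of male flies with an RNA interference construct against Ugt35b, a UDP-glycosyltransferase, under a pan-glial inducible driver. Flies of 1 genotype were given EtOH, which leaves the driver off, or RU486, which turns it on, and 3 libraries per group were made at day 10. Library totals ranged from 10156909 to 12636787 counts, with a mean of 12260855 in EtOH and 10393070 in RU486. The comparison asked which transcripts differ in the head when Ugt35b is targeted in glia, a condition the study links to a shorter lifespan. No library with RU486 and driver but without the construct was analysed here, so each difference is that of the drug and the knockdown together. Transcripts of ninaE, the main rhodopsin of the eye, took between 3.62% and 4.48% of the counts in each library. The muscle marker Mhc was at 1531 to 1934 CPM without TMM factors. Eye and muscle transcripts were thus present in every library, which argues against brain tissue alone.

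The target of the construct, Ugt35B1 (FBgn0026314, chromosome 3R, 11168503 to 11170246, minus strand), was lower in RU486. It was at 143 ± 5.47 CPM (SD, n = 3) in EtOH and 98.0 ± 12.6 CPM in RU486, a log2 fold change of -0.54 with an SE of 0.09 and an adjusted p of 0.00865. All 3 RU486 libraries, at 106, 83.5 and 104 CPM, lay below the lowest EtOH library at 136 CPM. The construct was driven in glia and the libraries held other cells too, so this fall does not measure the knockdown within glia. Among other genes called, the glial genes wrapper, Gat and zyd fell, as did 7 of 22 odorant-binding protein genes, 4 of 18 lipid droplet and transport genes and 5 of 20 neuropeptide genes, while 9 of 25 humoral immune genes and 4 of 12 clock genes rose. Each of these 6 lists was called at camera's preset correlation and none with an estimated correlation (adjusted p = 0.526 for glia and 0.332 for the others). Of 8945 genes tested, 683 were called, 390 higher and 293 lower in RU486, and 156 of them changed at least 2-fold, 113 higher and 43 lower. The groups did not overlap for 676 of the 683 calls. They did not overlap for 27.3% of all tested genes, against 10% by chance. The target's call was lost without EtOH replicate 3 (log2 fold change -0.52, adjusted p = 0.0566). The number of calls was 399 without EtOH replicate 1, 1441 without EtOH replicate 2, 341 without EtOH replicate 3, 440 without RU486 replicate 2 and 402 without RU486 replicate 3, and 290 genes, 183 higher and 107 lower, were called in all 6 fits that left out 1 library.

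**Figure D1:**
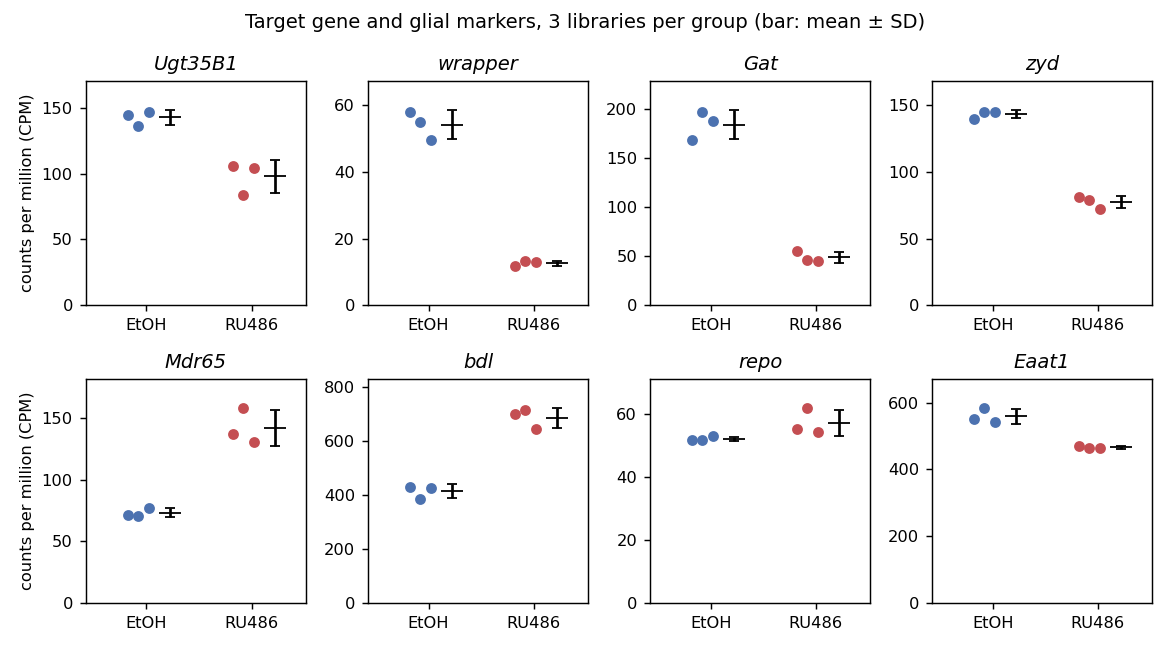
Levels of the target gene and of glial markers in CPM, with 1 point per library and a bar for the mean ± SD of 3 libraries per group. Ugt35B1, wrapper, Gat and zyd lay lower in every RU486 library than in every EtOH library, Mdr65 and bdl lay higher, and repo (52.1 and 57.2 CPM) did not pass the test.

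Among the 10 largest rises, Mco4, a multicopper oxidase, went from 6 counts summed over the EtOH libraries to 642 in RU486, and Osi6, an Osiris family gene, from 8 to 632. Mco4 was at 4.35, 31.7 and 26.3 CPM in RU486 replicates 1 to 3, thus higher in replicates 2 and 3, where digestive transcripts were high as well. The cuticle protein genes Cpr49Ac and Cpr49Ab rose from 2.32 ± 1.67 to 75.9 ± 3.25 CPM and from 0.616 ± 0.384 to 9.14 ± 0.965 CPM. The uncharacterised genes l(2)k05911 (log2 fold change 4.34, SE 0.29), CG11898 (3.98, SE 0.30), CG14752 (3.73, SE 0.43) and CG8736 (3.49, SE 0.20) also rose. The amylase genes Amy-p (6.37, SE 1.30) and Amy-d (4.79, SE 1.13) completed the 10, but their RU486 values too were spread widely, 354 ± 402 and 555 ± 682 CPM. CG11898 overlaps a gene on the other strand, and the 2 amylase genes are near-identical copies whose reads cannot be told apart with certainty. Neither amylase gene remained called without EtOH replicate 1 (adjusted p = 0.117 and 0.161) or without EtOH replicate 3 (0.128 and 0.176), and Amy-d was also lost without EtOH replicate 2 (0.078) or RU486 replicate 3 (0.0692). The calls of Mco4, Amy-p and Amy-d were lost with the robust prior (adjusted p = 0.0560, 0.153 and 0.201) and with limma-voom (0.107, 0.328 and 0.195).

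The largest falls were in CG4476, which went from 183 counts over the EtOH libraries to 6 in RU486, and in Obp99b, from 147 ± 40.9 to 6.54 ± 3.24 CPM. Lsp1beta, a storage protein of the hemolymph, fell from 106 ± 43.6 to 9.26 ± 4.65 CPM. CG9377 (log2 fold change -2.95, SE 0.31), CG40470 (-2.45, SE 0.10), CG3270 (-2.42, SE 0.16) and wun2, a lipid phosphate phosphatase gene (-2.27, SE 0.21), fell as well. Obp44a, the most abundant of these genes (chromosome 2R, 8134170 to 8135315), fell from 1147 ± 109 to 238 ± 12.8 CPM. The glial genes wrapper and Gat completed the 10 largest falls. CG40470 overlaps non-coding genes on both strands, and CG3270 and Obp44a each overlap a gene on the other strand.

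Glial genes moved in both directions. Of 19 measured glial markers, 3 fell, 2 rose and 14 did not pass the test. The gene wrapper, which codes for an immunoglobulin-family membrane protein of glia (chromosome 2R, 22379637 to 22382675), was 4.29-fold lower at 54.2 ± 4.33 CPM in EtOH and 12.6 ± 0.739 CPM in RU486. Gat, the GABA transporter of astrocyte-like glia (chromosome 4, 629691 to 635350), was 3.79-fold lower at 185 ± 14.6 and 48.7 ± 5.40 CPM. The cation exchanger gene zyd, known from cortex glia, fell from 143 ± 3.06 to 77.4 ± 4.59 CPM. Mdr65, a transporter gene of the blood-brain barrier, rose from 73.1 ± 3.66 to 142 ± 14.5 CPM, and bdl rose from 413 ± 25.5 to 685 ± 36.1 CPM. These 5 genes were called in all 6 fits that left out 1 library. The glial genes repo (log2 fold change 0.13, SE 0.08), nrv2 (0.07, SE 0.07), Gs2 (-0.00, SE 0.07) and Eaat1 (-0.26, SE 0.07, adjusted p = 0.0604) did not pass. Eaat1 was nonetheless lower in every RU486 library (453 to 468 CPM without TMM factors) than in every EtOH library (552 to 584 CPM). The genes moody, alrm and Tret1-1, which lie inside other genes, were not measured. Adjusted over the list alone, 7 members were called, 3 higher and 4 lower. Its median was -0.00, and camera called the list lower (adjusted p = 0.0403; adjusted p = 0.526 with an estimated correlation). That call was lost with DESeq2 size factors (0.0519), with the stricter filter (0.0621), and without EtOH replicate 1 (0.158), EtOH replicate 2 (0.552), EtOH replicate 3 (0.0746) or RU486 replicate 3 (0.0765).

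Some relatives of the target and some other detoxification genes fell. In the Ugt family, 5 of 20 measured members fell, 0 rose and 15 did not pass. Besides the target these were its neighbours Ugt35A1 (log2 fold change -0.33, SE 0.08) and Ugt35E2 (-1.51, SE 0.39), and Ugt35C1 (-0.72, SE 0.15) and Ugt302C1 (-0.27, SE 0.06). Adjusted over the list alone, 9 were called lower. Similar sequence within the family leaves open which member some reads came from. None of the 5 was called in all 6 fits that left out 1 library, and the number lower ranged from 1 (without EtOH replicates 1 or 3, or RU486 replicates 1 or 3) and 2 (without RU486 replicate 2) to 6 (without EtOH replicate 2). Ugt35A1 and Ugt35E2 (adjusted p = 0.04996 with all libraries) were called in none of these fits, and Ugt35A1 was also lost without a filter (adjusted p = 0.0709), with the replicate block (0.0578), the DESeq2 Wald test (0.102), limma-voom (0.0520) or the length correction (0.0512), an alternative chosen after seeing the data. Among 58 cytochrome P450 genes, 9 fell, 1 rose and 48 did not pass, and 13 were called when adjusted over the list alone. Cyp28d1 (-0.59, SE 0.09), Cyp4e3 (-1.20, SE 0.19), Cyp4s3 (-0.72, SE 0.12) and Cyp309a2 (-0.75, SE 0.13) fell, and these 4 were called in all 6 of those fits. The number lower was 4 without RU486 replicate 3, 5 without EtOH replicates 1 or 3 and 14 without EtOH replicate 2. Of 31 glutathione S-transferase genes 3 fell, 0 rose and 28 did not pass, with 5 called when adjusted over the list alone. GstE2 went from 32.3 ± 2.76 to 15.2 ± 1.82 CPM, and GstD5 (-1.34, SE 0.26) and GstS1 (-0.25, SE 0.06) fell too. GstE2 was called in all 6 fits that left out 1 library, GstD5 in 3 and GstS1 in 2, and GstS1 was lost with the replicate block (adjusted p = 0.0546) or limma-voom (0.0503). There was 1 member lower without EtOH replicate 3 or RU486 replicate 3, and 8 without EtOH replicate 2. With the length correction the median of the glutathione S-transferase list, of short genes (median exonic length 887 bases), went from -0.17 to -0.08. The medians of the Ugt and cytochrome P450 lists went from -0.26 to -0.24 and from -0.25 to -0.23. All 3 lists were called lower by camera (adjusted p = 7.48e-05, 7.48e-05 and 0.000577), and none with an estimated correlation (adjusted p = 0.332, 0.349 and 0.457 with an estimated correlation). The glutathione S-transferase list did not pass fry (adjusted p = 0.0753), which asks whether a list's genes move on balance one way and, unlike camera, does not compare them with other genes.

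Genes that make and store lipid were among those that fell. Fat body markers, described below, moved with them, as 5 of 12 fell, among them Obp99b (22.4-fold) and Lsp1beta (11.4-fold). Of 23 measured genes of fatty acid and triglyceride synthesis, 8 fell, 0 rose and 15 did not pass, and 9 were called lower when adjusted over the list alone. AcCoAS, which makes acetyl-CoA from acetate, fell from 1514 ± 209 to 834 ± 44.2 CPM. Men, the cytosolic malic enzyme that supplies NADPH, fell from 1222 ± 183 to 739 ± 50.6 CPM. ATPCL, the ATP citrate lyase, and Acsl, a long-chain acyl-CoA synthetase, fell by 0.49 and 0.43 on the log2 scale, and Dgat2, of the last step of triglyceride synthesis, by 1.10. Camera called this list lower (median log2 fold change -0.17, adjusted p = 0.000364; adjusted p = 0.332 with an estimated correlation). Of 18 genes of lipid droplets and lipid transport, 4 fell, 0 rose and 14 did not pass, and 5 were called lower when adjusted over the list alone. The lipid droplet protein gene Jabba fell from 278 ± 26.4 to 140 ± 10.1 CPM. The perilipin genes Lsd-2 and Lsd-1 fell from 644 ± 29.8 to 423 ± 19.7 CPM and from 488 ± 75.4 to 294 ± 34.3 CPM, and the sterol-binding protein gene Npc2a by 0.38 on the log2 scale. This list was also called lower (median -0.08, adjusted p = 0.0213; adjusted p = 0.332 with an estimated correlation), a call lost without RU486 replicate 3 (0.0580). AcCoAS, Men, Jabba and Lsd-2 were called in all 6 fits that left out 1 library, ATPCL and Lsd-1 in 5, Dgat2 in 4, Acsl in 3 and Npc2a in 2, and Npc2a was lost with the length correction (adjusted p = 0.0654). Across those fits the synthesis list had from 2 (without RU486 replicate 3) to 10 (without EtOH replicate 2) genes lower, with 5 without EtOH replicate 1 and 4 without EtOH replicate 3 or RU486 replicate 2. The droplet list had from 2 (without RU486 replicate 3) to 6 (without EtOH replicate 2). Of 16 genes of lipolysis and fatty acid oxidation, edgeR called 0 (median -0.08, list adjusted p = 0.0875), also when adjusted over the list alone, with 5 at an unadjusted p under 0.05 and 2 called by the DESeq2 Wald test. The list passed without EtOH replicate 2 (0.0231), where 3 members were lower, EtOH replicate 3 (0.0391) or RU486 replicate 2 (0.0399). In sphingolipid metabolism 1 of 17 genes, the ceramidase gene CDase, rose, from 132 ± 7.38 to 187 ± 1.12 CPM, and it was the 1 call adjusted over the list alone (list adjusted p = 0.378).

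Humoral immune genes were among those that rose. Of 25 measured genes of antimicrobial peptides and humoral immunity, 9 rose, 0 fell and 16 did not pass, and 14 were called when adjusted over the list alone, 13 higher and 1 lower. Among the 9 were short peptides of the Bomanin family, known as targets of the Toll pathway. BomBc3 rose from 19.3 ± 5.34 to 67.1 ± 8.23 CPM, BomBc1 from 6.04 ± 2.05 to 19.7 ± 3.23 CPM and BomBc2 from 156 ± 22.6 to 285 ± 35.6 CPM. The gene pirk, a known inhibitor of the Imd pathway, rose from 4.67 ± 1.75 to 21.9 ± 1.28 CPM, and Drs, which codes for the antifungal peptide Drosomycin, by 2.67 (SE 0.39) on the log2 scale. Camera called the list higher (median log2 fold change 0.49, adjusted p = 1.22e-09; adjusted p = 0.332 with an estimated correlation), and fry's test against no change did not pass (adjusted p = 0.0558). Bomanin genes are short paralogs, so part of their reads may be shared. Between 7 (without EtOH replicate 3) and 10 (without EtOH replicates 1 or 2) members were higher when a library was left out, 14 with the replicate block and 13 with the length correction.

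Some odorant-binding protein and fat body genes fell. Of 22 odorant-binding protein genes, 7 fell, 1 rose and 14 did not pass, and 15 were called when adjusted over the list alone, 14 lower and 1 higher. Besides Obp44a and Obp99b, Obp56g fell from 157 ± 7.31 to 82.9 ± 15.3 CPM, and Obp57a rose from 41.4 ± 2.49 to 62.2 ± 1.38 CPM. The list had the smallest adjusted p of the 28 lists tested (median -0.41, adjusted p = 7.40e-10; adjusted p = 0.332 with an estimated correlation). Leaving out 1 library gave from 4 lower (without EtOH replicates 1 or 3, or RU486 replicate 2) to 13 (without EtOH replicate 2), and the replicate block and the length correction gave 11 each. Of 12 fat body markers, 5 fell, 1 rose and 6 did not pass, with 8 called when adjusted over the list alone. Obp99b and Lsp1beta, given above, and the yolk protein gene Yp1 (log2 fold change -1.72, SE 0.42) fell, while Tsf1, the transferrin gene, rose from 1432 ± 193 to 2674 ± 345 CPM. This list was called lower (median -0.21, adjusted p = 0.00160; adjusted p = 0.332 with an estimated correlation), a call lost without EtOH replicate 2 (0.0586). Only 2 members, Lsp1beta and Obp99b, were lower in every fit that left out 1 library, and the number lower was 2 without EtOH replicate 1 or any 1 RU486 library and 3 without EtOH replicate 3. Yp1 was called in 1 of those fits and was lost with limma-voom (adjusted p = 0.102).

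Some neuropeptide genes fell and some clock genes rose. Of 20 neuropeptide genes, 5 fell, 0 rose and 15 did not pass, and 8 were called when adjusted over the list alone, 7 lower and 1 higher. Nplp3 fell from 345 ± 36.2 to 143 ± 7.26 CPM, Pdf, the peptide of clock neurons, from 54.2 ± 4.42 to 33.7 ± 2.94 CPM, and SIFa from 11.7 ± 1.31 to 5.24 ± 0.960 CPM. AstC (log2 fold change -0.41, SE 0.10) and CCAP, at 1.73 ± 0.315 and 0.257 ± 0.243 CPM, were the other members called. The list was called lower (median -0.25, adjusted p = 1.05e-05; adjusted p = 0.332 with an estimated correlation). Nplp3, Pdf and SIFa were called in all 6 fits that left out 1 library, and without EtOH replicates 1 or 3 or RU486 replicate 2 there were 3 members lower. The list median was -0.12 without EtOH replicate 3 and -0.14 with the length correction. AstC and CCAP were each called in 2 of the 6 fits, and CCAP was lost without a filter (adjusted p = 0.0585). Of 12 circadian clock genes, 4 rose, 1 (Pdf) fell and 7 did not pass, with 6 called when adjusted over the list alone. The genes were tim (210 ± 3.78 to 379 ± 28.5 CPM), per (64.1 ± 6.49 to 106 ± 8.20 CPM), cwo (92.7 ± 4.40 to 147 ± 6.08 CPM) and vri (74.4 ± 3.98 to 115 ± 6.75 CPM). The list was called higher (median 0.17, adjusted p = 0.0124; adjusted p = 0.332 with an estimated correlation), and all 5 genes kept their calls in the 6 fits that left out 1 library. The hour of collection is not given in the sources used here. The list fixed as immediate-early and activity-regulated genes also holds genes of stress and cell death, so it does not stand for activity alone. Of its 11 members, Mmp1 (160 ± 18.5 to 380 ± 33.3 CPM), kay (222 ± 13.5 to 318 ± 4.79 CPM) and puc (0.30, SE 0.07) rose. All 3 are also in the JNK list under other observations. In the immediate-early list Hr38 (-0.42, SE 0.09) fell and 7 members did not pass. That list was called higher (median 0.30, adjusted p = 0.0133; adjusted p = 0.332 with an estimated correlation), with 6 members called when adjusted over the list alone. Its calls of Mmp1 and kay held in those 6 fits. The call of puc was lost without any 1 library other than EtOH replicate 2 (adjusted p from 0.0633 to 0.142), and that of Hr38 without EtOH replicate 3 (0.0947), RU486 replicate 1 (0.0773) or RU486 replicate 2 (0.0616).

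**Figure D2:**
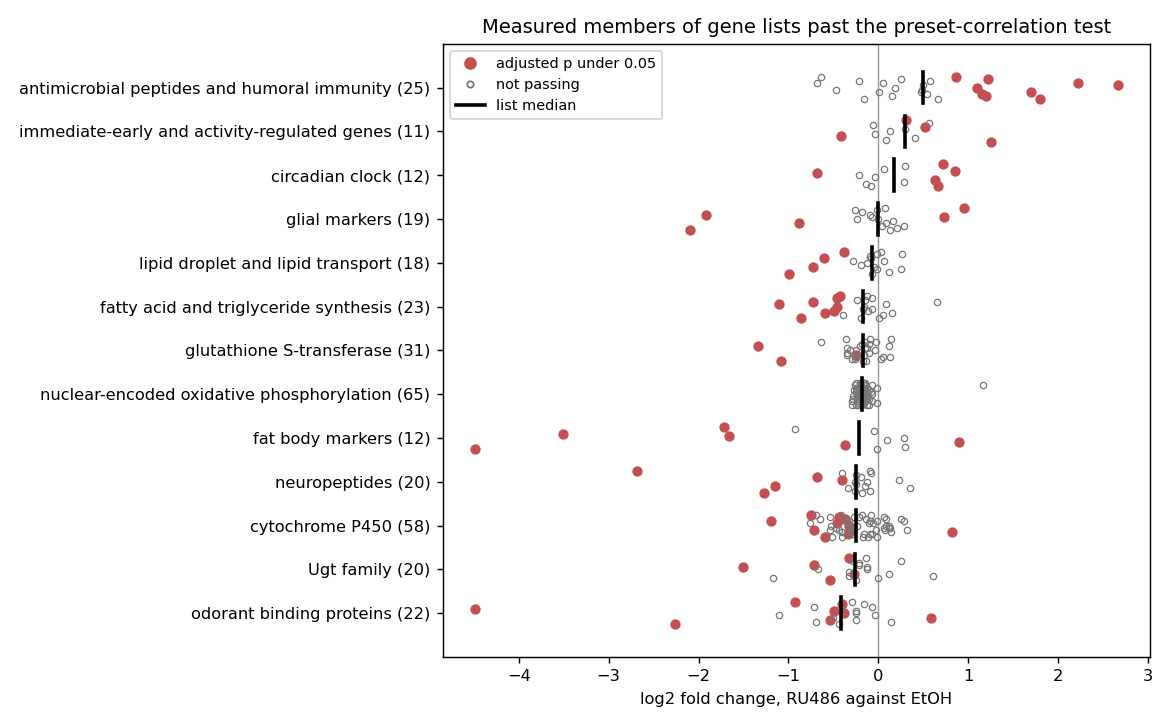
Log2 fold change (RU486 against EtOH, x axis) of each measured member of the gene lists past camera's preset-correlation test, other than the gut list. Filled points passed the adjusted p of 0.05, open points did not, bars are list medians and the number of measured members is in parentheses; medians ran from -0.41 for odorant-binding proteins to 0.49 for humoral immunity.

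Oxidative phosphorylation genes were called lower as a list and not singly. Of 65 measured nuclear-encoded oxidative phosphorylation genes, edgeR called 0, also when adjusted over the list alone, with 25 at an unadjusted p under 0.05, 2 called by the DESeq2 Wald test and 1 by limma-voom. The list was called lower by camera (median log2 fold change -0.18, adjusted p = 1.00e-05; adjusted p = 0.643 with an estimated correlation), and fry's test against no change did not pass (adjusted p = 0.129). Its members with the smallest p were UQCR-Q (-0.29, SE 0.08), ND-13B (-0.27, SE 0.08), ATPsynbeta (-0.22, SE 0.07) and ND-ASHI (-0.25, SE 0.08). UQCR-Q was called with DESeq2 size factors (adjusted p = 0.0476), library size alone (0.0454), upper-quartile factors (0.0397), the stricter filter (0.0432), the robust prior (0.0401) and the replicate block (0.0434), and ND-13B with upper-quartile factors (0.0458). Without EtOH replicate 2, 33 members were called lower. That library also stood apart from its group in a trend with transcript length: across genes, Spearman's rho between exonic length and a library's deviation from the mean was 0.337 there, -0.465 and -0.385 in the other EtOH libraries, and 0.132, 0.231 and 0.216 in RU486 (genes are not independent replicates). These are short transcripts, with a median exonic length of 871 bases against 2193 for all tested genes. In glycolysis and trehalose metabolism, 4 of 16 genes fell, 1 rose and 11 did not pass, with 8 called when adjusted over the list alone. Treh, the trehalase gene, fell from 735 ± 58.2 to 462 ± 8.76 CPM and Tps1, of trehalose synthesis, from 889 ± 85.9 to 564 ± 64.9 CPM; PyK fell by 0.29 and Hex-A rose by 0.35 on the log2 scale. The list did not pass (adjusted p = 0.0839), but did without EtOH replicate 2 (0.00806) or RU486 replicate 2 (0.0276). PyK and Hex-A were called in 1 of the 6 fits that left out 1 library each, and Treh and Tps1 in all 6. Without EtOH replicate 2, 8 members were lower, and without any 1 other library 2. In insulin, TOR and adipokinetic signalling, 4 of 20 genes rose, 2 fell and 14 did not pass, with 9 called when adjusted over the list alone. AkhR, the receptor of adipokinetic hormone, fell from 92.0 ± 8.53 to 54.8 ± 1.62 CPM, and Sesn (0.58, SE 0.07), srl (0.60, SE 0.09) and InR (0.71, SE 0.12) rose; the list did not pass against other genes (adjusted p = 0.109) and passed fry's test against no change (adjusted p = 0.0252), and InR was lost without EtOH replicate 1 (0.0618). The number higher was 2 without EtOH replicate 1 and 7 without EtOH replicate 2, and the number lower was 1 without EtOH replicate 3.

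Digestive transcripts differed between libraries of the RU486 group. Of 10 measured gut markers, Amy-p and Amy-d rose, LManII fell from 653 ± 28.4 to 450 ± 13.4 CPM and 7 did not pass, although 10 were called when adjusted over the list alone, 9 of them higher. Without LManII, the genes of the list, tested or not, summed to 50.6, 73.2 and 37.4 CPM in the EtOH libraries, to 40.5 CPM in RU486 replicate 1, to 11051 CPM in RU486 replicate 2 and to 884 CPM in RU486 replicate 3. Jon65Aiii, a digestive protease gene, was at 2.33 ± 1.87 CPM in EtOH and 571 ± 899 CPM in RU486 (adjusted p = 0.0558). Camera called the gut list higher (median 5.79, adjusted p = 0.0213; adjusted p = 0.636 with an estimated correlation), but not without RU486 replicate 2 (0.183) or EtOH replicate 2 (0.128), and fry's test against no change did not pass (adjusted p = 0.412). The gut list's median was 2.82 without RU486 replicate 2, and -1.76 over 12 measured members with RU486 replicate 1 alone against EtOH. With the replicate block 7 members were higher. The number higher was 8 without RU486 replicate 1, 1 without EtOH replicate 2 or RU486 replicate 3 and 0 without EtOH replicates 1 or 3. Of the 79 tested genes at least 5 times higher in RU486 replicate 2 than in replicate 1, 10 were among the calls higher in RU486. With those 79 genes left out, an alternative chosen after seeing the data, 823 genes were called.

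**Figure D3:**
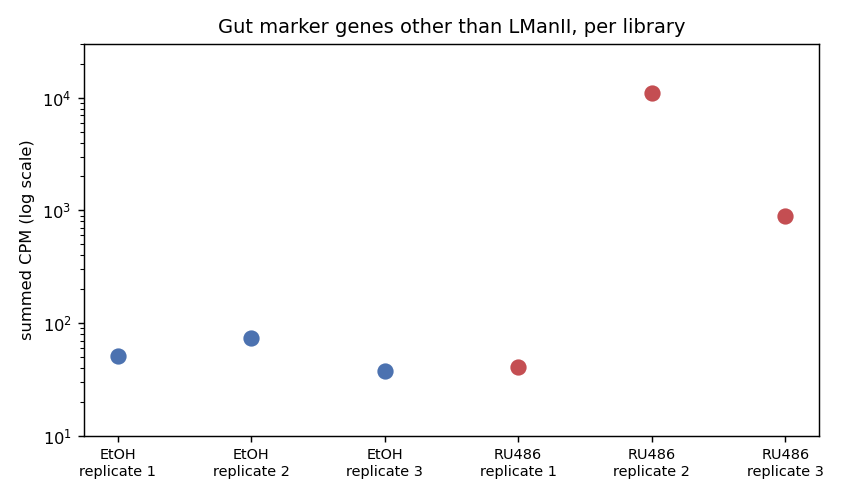
Summed CPM of the gut marker genes other than LManII in each library, on a log axis, with 1 point per library. RU486 replicates 2 and 3, at 11051 and 884 CPM, lay above the 3 EtOH libraries (37.4 to 73.2 CPM), and RU486 replicate 1, at 40.5 CPM, lay among them.

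The remaining lists, of other cell types and of stress and housekeeping genes, were not called by camera. Of 16 neuronal markers none passed (median log2 fold change -0.01, adjusted p = 0.515), with Gad1 at -0.31, VGlut at -0.33 and Snap25 at -0.27. None of 22 photoreceptor genes passed either (median -0.13, adjusted p = 0.113). Adjusted over each list alone, edgeR called 0 in both, with 4 neuronal and 10 photoreceptor genes at an unadjusted p under 0.05 and 3 of each called by the DESeq2 Wald test. The neuronal list passed without EtOH replicate 1 (0.0458) and the photoreceptor list without EtOH replicate 3 (0.0419), both lower. Without EtOH replicate 2, 7 neuronal markers were called higher and 1 lower, and 2 photoreceptor genes higher and 6 lower. Without EtOH replicate 1, 1 neuronal marker was called lower. The length correction called 4 of each list lower and the replicate block 1 photoreceptor gene. Gad1 was called with upper-quartile factors (adjusted p = 0.0421), the robust prior (0.0416) and limma-voom (0.0482), and the photoreceptor gene inaD with upper-quartile factors (0.0472), the robust prior (0.0422) and the replicate block (0.0454). Upper-quartile factors also called the photoreceptor genes Cds (0.0438) and gl (0.0499). Of 10 hemocyte markers, Pxn (203 ± 6.37 to 459 ± 42.8 CPM) and Ppn (433 ± 7.77 to 620 ± 28.4 CPM) rose, PPO2 (91.7 ± 15.7 to 55.3 ± 9.16 CPM) fell and 7 did not pass (list adjusted p = 0.213, and 0.0474 in fry's test against no change; 3 called adjusted over the list alone). PPO2 was lost without EtOH replicate 1 (0.0885), EtOH replicate 3 (0.109) or RU486 replicate 3 (0.0820). Of 17 muscle markers, Act79B alone fell (-0.46, SE 0.11), as it did adjusted over the list alone, and the list did not pass (0.460). Its call was lost in every fit that left out 1 library except the fit without EtOH replicate 1, and with limma-voom (0.0577) or the length correction (0.0715). Without EtOH replicate 2, 2 other muscle markers were called higher. Of 30 cuticle protein genes, 3 rose, 5 fell and 22 did not pass, with 9 called when adjusted over the list alone. Cpr100A (7.48 ± 2.64 to 27.3 ± 4.04 CPM) rose with the Cpr49A genes given above, and Cpr76Bc (38.3 ± 5.59 to 12.7 ± 1.58 CPM) fell. The list did not pass (adjusted p = 0.471), and its median of -0.19 and mean of 0.22 differed in sign. The number lower was 2 without EtOH replicates 1 or 3 and 3 without RU486 replicate 3. Among 16 antioxidant enzymes, Cat rose (0.35, SE 0.08), Sod3 (-0.53, SE 0.09) and Sod2 (-0.32, SE 0.07) fell and 13 did not pass (list adjusted p = 0.967; 8 called adjusted over the list alone). Of these, Sod3 alone was called in all 6 fits that left out 1 library, and Cat and Sod2 in 2 each. Cat was also lost with upper-quartile factors (0.0556) or without a filter (0.0571), and without EtOH replicate 2 there were 3 members higher and 5 lower. Of 12 heat shock genes, DnaJ-1 rose (0.41, SE 0.07), which was lost without RU486 replicate 3 (0.0515), and 2 were higher without EtOH replicates 1 or 2, while 11 did not pass (list adjusted p = 0.683; 5 called adjusted over the list alone). With edgeR, neither all-gene nor list-alone adjustment gave a call among 16 unfolded protein response genes (list adjusted p = 0.420), 23 of autophagy and the lysosome (0.938) and 78 cytosolic ribosomal proteins (0.938). At an unadjusted p under 0.05 there were 2, 2 and 0, and the DESeq2 Wald test called 0, 1 and 0. For autophagy and ribosomal proteins the median, 0.01 and 0.00, was above 0 and camera's direction was down. The ribosomal list was called lower without EtOH replicate 2 (0.0161), with 3 members lower. Male reproductive tract genes summed to at most 0.591 CPM in any library. Across the 28 lists, 14 were called at the preset correlation, 4 higher and 10 lower. With an estimated correlation camera called 0, with 3 at an unadjusted p under 0.05, and fry, against no change, called 12, of which 10 were among those 14.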

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

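The test in this part was chosen after the digestive transcripts had been seen. RU486 replicate 2 held 53910 counts in genes too low for the test, above the highest EtOH library (7363) and above RU486 replicates 1 (6079) and 3 (8638). Of these, 45755 counts lay in 114 genes that had at least 50 counts in RU486 replicate 2 and less than 0.1 times that in RU486 replicate 1. The same 114 genes held 2447 counts in RU486 replicate 3 and 112 in RU486 replicate 1, where the low sum follows from how they were chosen. What these genes are was not examined. The 9 tested gut markers other than LManII ranked the RU486 libraries in the same order. They summed to 10729 CPM in RU486 replicate 2, 880 CPM in RU486 replicate 3 and 40.1 CPM in RU486 replicate 1.

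Of the 10 measured gut markers, 9 exceeded the highest EtOH library in each of RU486 replicates 2 and 3, and 2 in RU486 replicate 1. A candidate explanation is gut tissue carried into the material of RU486 replicate 2. Of 23 detected digestive genes outside the fixed gut list, 18 (78.3%) were at least 3 times higher in RU486 replicate 2 than in replicate 1, against 4.94% of all genes with 10 or more counts. A response of the RU486 flies stays open and was not tested. One of like size in all of them would have raised gut markers in RU486 replicate 1 too. There the gut list without LManII summed to 40.5 CPM, within the EtOH range of 37.4 to 73.2 CPM, but this is 1 library. A response in some of the flies could raise the same genes, so the count of digestive genes cannot tell it from gut tissue.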

How the results depend on the processing

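The length correction, the fit of RU486 replicate 1 alone and the removal of genes 5 times higher in RU486 replicate 2 were chosen after seeing the data. Calls numbered 610 without a filter, 668 with limma-voom, 699 with DESeq2 size factors, 712 with upper-quartile factors and 886 with the DESeq2 Wald test. Leaving out 1 library gave 341 to 1441 calls (214 to 853 higher, 127 to 588 lower), and Ugt35B1 ranged from -0.61 to -0.44; fewer libraries were fitted, yet the rise to 1441 came from omitting EtOH replicate 2, and its cause was not tested. A threshold of 0.01 gave 321 calls (204 higher, 117 lower) and 0.1 gave 1114 (611 and 503). The length correction gave 971, with 444 lower; it ended the clock list's call (0.0516) and the gut (0.0560) and glial (0.120) lists' calls and called ribosomal proteins higher (0.00593), neuronal (0.0197), photoreceptor (0.0109) and glycolysis (0.0337) lists lower, and the cause was not tested. It also called 2 oxidative phosphorylation and 2 lipolysis genes lower and 2 unfolded protein response and 2 ribosomal protein genes higher, where the count was 0 without it, and 3 cytochrome P450 genes higher. RU486 replicate 1 alone, whose spread is assumed to equal that of EtOH, gave 198 calls (145 higher, 53 lower) and Ugt35B1 at -0.41 (adjusted p = 0.280); of the 682 calls that could be tested there, 5 changed sign. Jon65Aiii was then at -2.93 (adjusted p = 0.494) and the gut list was called lower (adjusted p = 0.00551), and the cause was not tested. Camera with an estimated correlation called 0 lists (3 at an unadjusted p under 0.05) and fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, 12. The replicate numbers may only name libraries. Deviations of same-numbered libraries from their group means correlated at 0.124, 0.269 and -0.0441, which does not settle it. EtOH replicate 3 went best with RU486 replicate 1, whereas EtOH replicate 2 went best with RU486 replicate 2. With the replicate block 872 genes were called, 653 of them among the 683, and the glycolysis list was called lower (0.0300). Small changes could be missed, since simulated 1.5-fold changes were recovered in 43.9% of cases at this depth with 3 libraries per group. Whether depth, spread or the number of libraries set this limit was not tested.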

Other observations

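The 6 lists in the next 2 paragraphs, the test of the glial genes and the length correction were chosen after the results were seen. The criteria of the length-matched test and of the library splits were written before their outcome was known. Neither test was in the plan fixed before the data were examined. The length-matched test addresses a list call already seen, and its criteria refer to the length correction. Since these 6 lists were put together with their members' values in view, their counts do not show that a pathway moved, and the values below stand for single genes. Of 16 measured genes of the JAK/STAT pathway, 5 rose and 0 fell. The receptor gene dome rose from 84.7 to 215 CPM (log2 fold change 1.34, SE 0.07) and the feedback inhibitor Socs36E by 0.80 (SE 0.09), both called in all 6 fits that left out 1 library. The cytokine genes upd3 (2.27, SE 0.42) and upd1 (2.81, SE 0.63) and the stress gene TotM (2.38, SE 0.54), 1 of 3 measured Turandot genes, rose too, with calls in 4, 2 and 3 of those fits. Their levels were low, with upd3 from 0.90 to 4.44 CPM, upd1 from 1.54 to 11.1 CPM and TotM from 5.15 to 27.0 CPM. In the JNK pathway 6 of 16 genes rose and 1 fell, with Mmp1, kay and puc, given above, among the 6. Among those that rose were egr, the fly's TNF ligand, from 100.4 to 300.1 CPM (1.58, SE 0.19), and the transcription factor gene Ets21C (1.75, SE 0.22), both called in all 6 fits, whereas puc, wgn and bsk, the gene that fell (-0.30, SE 0.07), were each called in 1. Of 11 Toll pathway components 3 rose, namely spz (1.27, SE 0.11), dl (0.61, SE 0.07) and grass (0.72, SE 0.10).

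Of 19 measured genes of the extracellular matrix and basement membrane, 8 rose and 0 fell. Tig, an integrin ligand, rose from 141 to 704 CPM (2.32, SE 0.12), and Ndg, the nidogen gene, by 1.40 (SE 0.14). The laminin genes LanB2 and LanB1 rose by 0.49 and 0.35, with LanB1 called in 2 of the 6 fits that left out 1 library. Of 10 genes of phosphatidylethanolamine and phosphatidylcholine synthesis, Pcyt2 fell from 92.8 to 38.9 CPM (-1.25, SE 0.08). CG7149 rose from 101 to 146 CPM (0.53, SE 0.06), and both were called in all 6 fits. Of 12 ecdysteroid genes 2 rose and 1 fell. The biosynthetic genes sad and phtm rose from 5.78 to 57.9 CPM (3.31, SE 0.40) and from 1.42 to 8.88 CPM (2.63, SE 0.37), while shd, of the last step to the active hormone, fell by 1.58 (SE 0.31) and was called in 4 of the 6 fits.

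The falls of wrapper, Gat and zyd stood against a glial list whose other 16 members had a median log2 fold change of 0.056 and a median absolute deviation of 0.20. That median lies well above -0.89, the smallest of the 3 falls. The 3 genes were set apart because they fell, which by itself raises the median of the rest. Over all 19 measured members, however, the median was -0.00, and the lowest of the other 16 was at -0.26. These values argue against a loss of glia of all kinds as large as the smallest of the 3 falls. They cannot exclude a smaller one. A loss or a changed state of the glial classes that carry these transcripts stays open. Either may follow from the knockdown or from RU486 itself, and the design holds no library that separates the knockdown from the drug.

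The lower oxidative phosphorylation list could reflect the trend with transcript length, since log2 fold changes rose with exonic length across genes (Spearman's rho 0.278). Random lists matched on length and mean expression had a median log2 fold change of -0.07, against -0.18 for the list. The list lay at percentile 0.07 of 10000 such lists, below their lower limit of -0.14. After the length correction camera still called it at the preset correlation (adjusted p = 0.000964), but its median moved from -0.18 to -0.08. The matched lists were themselves below 0 and drew genes without regard to how they vary together. The genes of this list were correlated, at an estimated 0.647. Neither test can therefore settle whether length was the whole cause, and the list call stays open.

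Of the 10 splits of the 6 libraries into groups of 3, the real one gave 683 calls and the highest of the others 0. Only 1 split, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. Every other split also put EtOH and RU486 libraries together in both groups. Any difference between the treatments then adds to the spread within groups and lowers the number of calls. The count of 0 is therefore no measure of what unrelated groupings would give.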
